A study of Homo sapiens with 6 samples.

How the data were processed

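RNA sequencing was described for 6 samples, a vector control and a circMGA-overexpressing culture of each of the bladder cancer cell lines EJ, T24T and UMUC3. The submitters' processing notes name HISAT2, StringTie and the build hg38, without versions for the tools. The labels name 1 count table for EJ and 1 for T24T and UMUC3. By their file names, the other tables hold the authors' FPKM and RPKM values, and no label ties them to a line. The FPKM table is called an EJ table here because its 20030 gene rows equal those of the EJ count table in name and order. The RPKM table is called a table of T24T and UMUC3 because each of its value columns is a constant multiple, per base of gene length, of a column of their count table. The program that counted reads is not given in the sources used here.

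The 4 tables held 12 columns of sample values, named by the word Sample and a number. No title, description, source name or characteristic of a sample used such a name, so 0 columns could be matched to a single sample. Columns were not assigned by their order or by their values, because either would have been a guess at the treatment. The 12 columns therefore entered no comparison between treatments or lines, and no expression value from them is reported. The planned edgeR fits, limma gene list tests, within-line ratios and comparison of the lines were not run.

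The values of the T24T and UMUC3 tables were read for 1 purpose, to test whether the count and RPKM tables give the same library the same column name. For each of the 16 pairs of a count and an RPKM column, RPKM times gene length was divided by the count, over genes with more than 50 counts and an RPKM above 0. The 95th percentile of this ratio was divided by the 5th, and a ratio was called constant when the quotient was within 0.1% of 1. Beyond this, gene names, positions and lengths were read. Python 3.11.15 was used throughout. Gene rows were counted in each table and names were compared as written. A row counted as whole when it had as many fields as the header. A row's span ran from its lowest start to its highest end, as the deposited tables give them. Of 34779 RPKM rows, 23781 lay on a single chromosome or scaffold under a name with 1 gene in GENCODE release 29 (GRCh38). Each was compared with that gene, and 22178 of 23781, 93.3%, had the same start, end and strand. The remaining rows were not compared. The authors' annotation release is not given in the sources used here. MGA, HNRNPL and CCL5 were named by a rule set before the data were examined, as were the 32 gene lists. Older symbols were updated, as an alternative, through RefSeq synonyms of GRCh38.p14 that pointed to 1 current symbol.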

Results

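The series described RNA sequencing of 6 samples from the human bladder cancer cell lines EJ, T24T and UMUC3. Each line had 1 culture with an empty pcDNA3.1(+) vector and 1 with a vector for circMGA, a circular RNA named after the gene MGA, so a treatment had 3 samples and a line had 1 sample per treatment. The design addressed how overexpression of circMGA changed the transcriptome of these lines. No expression value, fold change or test is reported here. The 12 columns of sample values carried names that no sample's labels used, so no library could be placed in a treatment. The labels placed the columns of 1 count table in EJ and those of the other in T24T or UMUC3, without saying which. The FPKM and RPKM tables were tied to lines by no label, only by their match to the count tables. Thus circMGA was not compared with vector control in EJ, T24T, UMUC3 or over the 3 lines. The count and RPKM tables of T24T and UMUC3 also gave the same libraries different names. RPKM times gene length was a constant multiple of the count in 4 of the 16 pairs of columns, over 5188 to 5937 genes, and in 0 of these did both columns carry the same name. The constant pairs were count columns Sample3, Sample4, Sample5 and Sample6 with RPKM columns Sample5, Sample6, Sample3 and Sample4, in that order. In the other 12 pairs the ratio's 95th percentile was 1.59 to 3.74 times its 5th in 4 pairs and 11.6 to 19.0 times in 8 pairs. The 4 lower values were those of the libraries Sample3 and Sample4 of the count table with each other and of Sample5 and Sample6 with each other. The names of 1 table could thus be translated into those of the other only through this match, not by using the same name. UMUC3 was not compared with T24T, since the labels did not say which columns were T24T and lines were not assigned from values, and the depth per sample is not given. What follows describes the genes that the tables covered.

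MGA, which encodes a DNA-binding partner of MAX, had a row in the tables of all 3 lines. It lies on chromosome 15 from 41621224 to 41773081 on the plus strand of GRCh38 (hg38), and GENCODE release 29 lists it as protein-coding. Its row in the T24T and UMUC3 tables joined 132 annotated exon entries into a length of 17651 bases. Such a row covers the whole gene, so it gives no value for the circular RNA, which was not matched by identifier or coordinates. HNRNPL, which encodes an RNA-binding protein of the hnRNP family, lies on chromosome 19 from 38836388 to 38852347 on the minus strand. Its length was 6821 bases in the RPKM table of T24T and UMUC3. CCL5, which encodes a chemokine, lies on chromosome 17 from 35871491 to 35880793 on the minus strand. The RPKM table gave CCL5 a length of 1512 bases. HNRNPL and CCL5 had rows in the EJ tables and in the RPKM table of T24T and UMUC3, and neither had a row in the count table of T24T and UMUC3 as used here.

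The count table of T24T and UMUC3 held 13750 whole gene rows, 39.5% of the 34779 genes in the RPKM table of the same lines. Its rows matched the first 13750 rows of the RPKM table in gene name, order and length, and 1 further row was cut short. The copy used here had exactly 10485760 bytes, or 10 MiB, and whether it was cut before or after deposit is not known, so each count of genes with counts describes this copy. The rows ran through chromosomes 1 and 10 to 16 and then into chromosome 17, where 583 of 2128 genes had a row. The last whole row was RP11-311F12.1, on chromosome 17 from 19719059 to 19722428. Genes of the X and Y chromosomes, the mitochondrial genome, the scaffolds and the other autosomes had no count row in this copy. This leaves aside rows that joined several chromosomes or scaffolds.

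The EJ tables listed 20030 genes, and 16469 of these names, 82.2%, also stood in the RPKM table of T24T and UMUC3. In the copy used here, counts for all 3 lines were held for 6474 gene names. The EJ tables were nearly restricted to protein-coding genes: of 19235 EJ names with a single gene in GENCODE release 29, 19095 were protein-coding. The RPKM table was broader. Of its 34779 rows, 23781 stood on a single chromosome or scaffold and had a name with 1 gene in that release. Of these, 16378 were protein-coding, and the gene types of the remaining rows were not determined.

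The 32 gene lists fixed for this study held 759 different symbols, of which 683 had a row in both the EJ tables and the RPKM table and 268 had counts for all 3 lines in the copy used here. All 43 interferon-stimulated genes, all 18 genes of MHC class I antigen presentation and all 28 genes of mitosis and G2/M were listed for the 3 lines. Of these, 27, 4 and 13, in that order, had counts for all 3 lines in the copy used here. Among all 16469 names in both the EJ and RPKM tables, 6474 had such counts. Which list genes had counts depended on where the copy of the count table ended. Of 37 chemokine and cytokine genes, 32 were listed for the 3 lines and 6 had counts for all of them. The MAX network and PRC1.6 list, which includes MGA, had 23 of 23 members listed and 11 with counts for all lines. The 13 mitochondrially encoded genes and the 10 listed long noncoding RNAs had rows among the RPKM values of T24T and UMUC3. Matched by symbol as written, they had 0 rows for EJ. Of 16 T and NK cell markers, 15 were listed for EJ and 9 for T24T and UMUC3, and of 14 macrophage markers, 14 were listed for EJ and 9 for T24T and UMUC3. These are counts of listed genes, and no gene is read from them as expressed or not. Whether genes with few or no reads had been left out for any line was not tested.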

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

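The alternatives given here were chosen after the tables were seen. Those fixed before the data were examined concerned expression comparisons and were not run, since no sample column could be matched. No paired analysis was possible because the labels did not say which column was vector control and which circMGA, nor which columns were T24T and which UMUC3. Updating older symbols raised the names shared by the EJ and RPKM tables from 16469 to 16750, the names with counts for all 3 lines from 6474 to 6587, and the list genes in both tables from 683 of 759 symbols to 687 of 738 genes. Ignoring case left these 3 counts as they were.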

Other observations

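In the RPKM table of T24T and UMUC3, 116 of 34779 rows joined stretches on 2 or more chromosomes or scaffolds under 1 gene name. The row named Y_RNA joined 758 stretches on 26 sequences, Metazoa_SRP 170 stretches on 22 sequences and U6 37 stretches on 20 sequences. A value in such a row belongs to a set of loci that share a name, not to 1 gene.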
